A study of Lathyrus oleraceus with 4 samples.

How the data were processed

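RNA from pre-anthesis flower buds was sequenced in 4 samples, 1 per cultivar and treatment. Per the labels' protocols, the libraries were made with a SMARTER mRNA kit from total RNA. FastQC, STAR, Bowtie2, RSEM and DESeq2 are named in the submitters' processing notes, with no version, role or order. The genome build and the assembly settings are not given in the sources used here. The row names, per the file headers, are gene identifiers of the form that genome-guided Trinity assembly gives, where a cluster number is followed by a component and a gene number. The same 127533 identifiers stand in both cultivars' tables, in the same order. A transcriptome assembly can hold 1 gene as several entries, and estimated counts share reads between similar entries, so a value of 0 for an entry does not show that the gene was silent.

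For each cultivar the authors deposited 2 tables. The first holds expected counts, which the authors estimated per assembled gene, and its values are not whole numbers. They were taken as not normalized because the column totals are unequal, between 10411488 and 21625288 over the 2 cultivars. The second holds a signal that is the deposited count multiplied by 1 constant per column. It was marked as TMM by the authors, its columns sum to between 961675 and 1062644, and it has no gene length term. It was scaled separately for each cultivar, so it was used only as an alternative for ratios of heat to control within a cultivar and for comparing those ratios, not for levels between cultivars. Each library name carries 2 numbered columns. Since no label explains the numbers, the 2 columns were treated as 2 measurements of 1 sample and summed. Groups were taken from the sample titles, which disagree with the genotype tags as stated in the results. No label states that samples came from separate plants, and p-values then measure only the spread between these libraries.

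Expected counts were summed over the 2 columns and rounded to whole numbers for the exact intervals and the count tests. Library sizes were scaled with TMM in edgeR 4.0.16 under R 4.3.3. For heat against control within a cultivar no test across plants was possible, and the log2 ratio of CPM with a pseudocount of 0.5 CPM was used. A gene was counted as different when it reached 1 CPM in at least 1 of the 2 libraries, the ratio was at least 2-fold, and the exact (Clopper-Pearson) 95% interval of the ratio given the 2 counts excluded 1. The difference of the 2 responses was treated in the same way with the exact conditional interval of the odds ratio. Such intervals, and the limit of 3 counts used in place of a count of 0, cover counting error only. A limit of 3 counts is 0.0896 to 0.131 CPM in these libraries. The shared heat response and the shared cultivar difference were tested with edgeR's quasi-likelihood test (filterByExpr, adjusted p of 0.05 by Benjamini-Hochberg) on all 4 libraries with both factors in the model, which leaves 1 residual degree of freedom per gene. DESeq2 1.42.0 was the alternative. No comparison had 3 samples in a group, so other splits of the samples were not counted.

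The scripts were tested on simulated data for 77137 genes drawn from the real means, library sizes and dispersions, with 200 genes changed. The edgeR test of heat recovered 13.0% of genes changed 16-fold with 1 false call, and none changed 4-fold. The same test of cultivar recovered 14.5% of genes changed 16-fold. With counting noise alone, the 2-fold rule in Arka Chaitra recovered 96.5% of genes changed 4-fold, with 8 unchanged genes called. The rule for the difference of responses called 124 unchanged genes.

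The comparisons, tests, alternatives and the rule for naming genes were set before the data were examined. Within each cultivar the rule took the 6 genes of each direction with the largest log2 ratio among those past the 2-fold rule with 10 CPM or more in the higher library, and further genes from the edgeR calls, the difference of responses and the gene lists. Because the identifiers have no gene names, only the first gene of each direction in each cultivar is printed. The edgeR tests at the adjusted p called no gene, and genes from the difference of responses are not printed. Sets defined by product names (33 lists) and tests of lists against random lists could not be run, because 0 identifiers were paired with a name in the files or among the 65673 genes of the pea reference table, assembly CAAS_Psat_ZW6_1.0. Comparisons of single columns, sums over cluster numbers, fits with the columns as separate libraries and the windows of cluster numbers, with shuffles of results over genes within them, were added after seeing the data. Windows were assigned to a kind from the control libraries alone. Alternatives covered the scaling, the pseudocount, the filter on low counts, the deposited signal table, the block and the omission of each library.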

Results

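Gene expression was measured by RNA sequencing of unopened flower buds of pea (Pisum sativum, listed under its other name Lathyrus oleraceus), taken before anthesis, the opening of the flower. Plants of 2 cultivars, one described by the submitters as heat-tolerant (Arka Chaitra) and one as susceptible (Matar Ageta), were either kept at 22 °C by day and 16 °C by night or exposed to 35 °C for 2 h and harvested at once. The series holds 4 samples, 1 for each cultivar and treatment, so no group has a repeat at the level of the sample. The genotype tag and the title of each sample name opposite cultivars: the tag matched the title in 0 of 4 samples. Cultivars are named here by the title and the library name, and every statement about a cultivar applies to "the libraries titled" with that name. The treatment tags and the titles do not differ on heat or control. The batch tag reads genotype for every sample, so a batch that goes with the cultivar and the cultivar itself cannot be told apart.

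Each library appears as 2 numbered columns of estimated counts, and no label says whether the columns stand for separate plants, separate preparations or repeat sequencing. They were summed and counted as 1 sample. Summed totals were 24247298 estimated counts for the Arka Chaitra control, 22721707 for Arka Chaitra after heat, 30439930 for the Matar Ageta control and 32711024 for Matar Ageta after heat. Single columns held between 10411488 and 21625288. The counts refer to 127533 genes of a transcriptome assembly, which fall into 69607 numbered clusters. At least 1 CPM (the count scaled to library size), which is 23.0 to 33.5 reads depending on the library, was reached by 50280 and 54501 genes in the Arka Chaitra control and heat libraries and by 46198 and 44983 genes in those of Matar Ageta. The most abundant gene of a column took at most 0.725% of its counts. The identifiers carry no gene names, and 0 of them matched the pea reference gene table, so no gene, pathway or protein family could be named. Genomic positions were likewise not analysed here.

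The 2 columns of a library differed by far more than counting noise. Among genes with at least 100 counts over both columns, the median chi-square value was 3.39 in the Arka Chaitra control, 1.69 in Arka Chaitra heat, 8.45 in the Matar Ageta control and 5.43 in Matar Ageta heat, against 0.455 for counting noise alone. Among genes with at least 5 CPM in the higher of 2 columns, 18.8% to 24.4% differed at least 2-fold between columns of the same library. The share was 26.2% to 30.2% for the 4 pairs of a heat and a control column of Arka Chaitra, and 18.9% to 32.2% for the 4 such pairs of Matar Ageta. The range for Matar Ageta overlapped that within libraries, and the range for Arka Chaitra lay above it. Pairs of columns from different cultivars differed at least 2-fold in 48.8% to 52.4% of genes in the controls and in 52.3% to 57.2% after heat.

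**Figure D1:**
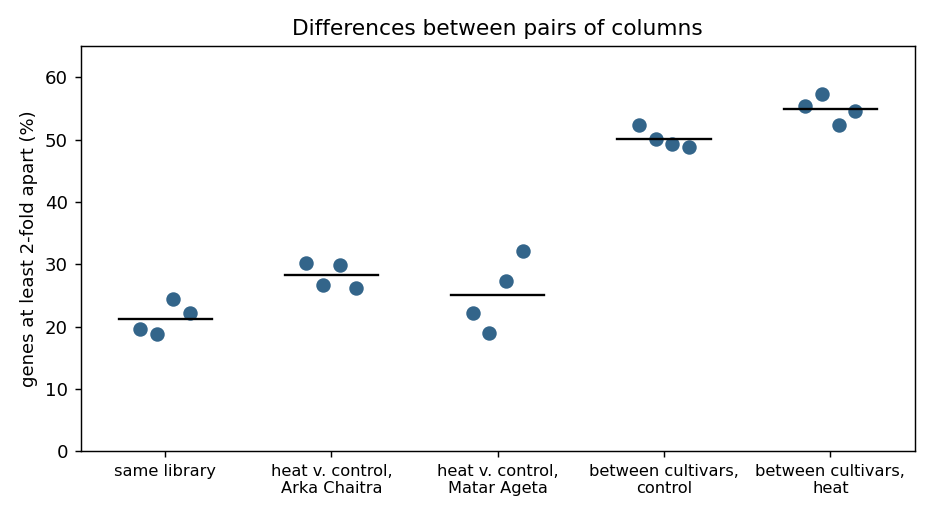
Percentage of genes at least 2-fold apart between 2 columns (vertical axis), among genes with at least 5 CPM in the higher column, by the kind of pair (horizontal axis). Each point is 1 pair of columns and each line is the mean of the 4 pairs; pairs within a library lie between 18.8% and 24.4%, and pairs between cultivars lie between 48.8% and 57.2%.

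The comparison of heat with control within Arka Chaitra addresses the response of buds to the brief heat episode in the cultivar described as tolerant. Of 63677 genes with at least 1 CPM in either library, 13372 (21.0%) were at least 2-fold higher after heat and 9120 (14.3%) at least 2-fold lower, with the exact 95% counting interval of the ratio excluding 1. At least 8-fold differences were found in 1842 genes that were higher and 913 that were lower. Among genes with at least 10 CPM in the higher library, 1515 were at least 2-fold higher and 1371 at least 2-fold lower. A large part of the higher genes, 8049 or 60.2%, had 3 counts or fewer in the control library, so the size of their ratio is poorly determined. Over all 63677 genes, both heat columns lay above both control columns in 25.1% and below them in 21.6%, where a random order of the columns gives 16.7% each. The gene with the largest ratio, pseudocount included, was TRINITY_GG_68082_c0_g1, with 1 count (0.0613 CPM) in the control and 21979 counts (957 CPM) after heat. Its log2 ratio was 10.74 with the pseudocount of 0.5 CPM. Without a pseudocount the log2 ratio was 13.93, with a counting interval of 11.96 to 19.74. Its heat columns held 983 and 955 CPM. The gene with the largest ratio in the other direction, TRINITY_GG_47631_c15_g1, was at least 7614-fold lower after heat (995 CPM in the control, 0 counts after heat, with 3 counts per library as the limit). That difference rested on 1 control column, which held 2180 CPM while the other control column held 0. In Matar Ageta the same gene differed the other way, from 0 counts to 3043 counts (90.8 CPM), at least 931-fold higher, and again in 1 column only (0 and 251 CPM). With 1 library per group there is no replicate check, and the intervals cover counting error only.

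Within Matar Ageta, which addresses the same response in the cultivar described as susceptible, 7718 of 54674 genes (14.1%) were at least 2-fold higher after heat and 9707 (17.8%) at least 2-fold lower. At least 8-fold differences were found in 662 and 1264 genes. With at least 10 CPM in the higher library, 702 genes were at least 2-fold higher and 1248 at least 2-fold lower. The control library held 3 counts or fewer for 57.4% of the higher genes, and the heat library for 56.6% of the lower genes. Over all 54674 genes, both heat columns lay above both control columns in 17.2%, near the 16.7% of a random order, and below them in 22.0%. TRINITY_GG_49330_c0_g1 had the largest ratio among higher genes and was at least 1067-fold higher after heat, from 0 counts to 3485 counts (104 CPM), although its 2 heat columns differed (60.8 and 181 CPM). TRINITY_GG_14073_c0_g1 had the largest ratio among lower genes and was at least 3601-fold lower, from 9920 counts (322 CPM, with columns at 97.5 and 563 CPM) to 0 counts. The first of these had 395 CPM in the Arka Chaitra control and 196 CPM after heat (log2 ratio -1.01). The second had 1362 CPM there in the control and 1100 CPM after heat (log2 ratio -0.31).

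A heat response shared by the cultivars was tested with edgeR's quasi-likelihood test on all 4 libraries, with the cultivar as a block, so that the spread was the disagreement between the 2 cultivars' responses. Of 77137 genes tested, 0 were higher and 0 were lower at an adjusted p of 0.05 (Benjamini-Hochberg). At an unadjusted p of 0.05 there were 1162 genes, fewer than the 3857 that chance alone gives, of which 606 were higher and 556 lower. DESeq2 with the same design called 56 higher and 9 lower genes. It was given all 127533 genes and gave no adjusted p for 86119 of them, so its tested genes differed from those of edgeR. The common biological coefficient of variation was 92.8% with 1 residual degree of freedom, and in simulated data of the same design the edgeR test recovered 26 of 200 genes changed 16-fold and 0 of 200 changed 4-fold. A shared 4-fold change was therefore not detected by that edgeR test when 200 of 77137 genes changed. Of these 200 simulated genes, 75 had an unadjusted edgeR p under 0.05. Calls after Benjamini-Hochberg adjustment depend on how many genes change, and the simulated means held no other difference between the cultivars. Other settings and DESeq2 were not simulated. TRINITY_GG_68082_c0_g1, the gene named above from Arka Chaitra, was also higher after heat in Matar Ageta, where it had 0 counts in the control and 989 counts (29.5 CPM) after heat, at least 303-fold. Its edgeR log2 fold change was 14.11 with an unadjusted p of 0.000252 and an adjusted p of 1.

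Without a test, the 2-fold differences of the cultivars overlapped more in the higher direction than independent lists would. Among 41591 genes with at least 1 CPM in either library of both cultivars, 1450 were at least 2-fold higher after heat in both, against 513 for independent lists, which is 2.83 times. In both cultivars 1138 genes were lower, against 799 for independent lists, which is 1.42 times. Opposite differences also exceeded independence: 1399 genes were higher in Arka Chaitra and lower in Matar Ageta against 842, and 854 genes went the other way against 486. The log2 ratios of the 2 cultivars correlated weakly across genes, with Pearson's r of 0.0547 and Spearman's rho of 0.0750. Genes are not independent replicates, so no p-value is given.

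The difference between the cultivars' responses, the question that the contrast of a tolerant and a susceptible cultivar raises, takes up every residual degree of freedom and has no test. The log2 ratio of heat to control was larger in Arka Chaitra by at least 1, with the exact counting interval excluding 0, in 12235 of 76760 genes (15.9%). It was larger in Matar Ageta by at least 1 in 8095 genes (10.5%). The 76760 genes reached 1 CPM in at least 1 of the 4 libraries, and 41591 genes reached it in both cultivars. A gene with no counts in 1 cultivar stayed among the 76760 but could not be counted as different. For a gene near absent in 1 cultivar, the pseudocount draws that cultivar's log2 ratio towards 0. The 12235 and 8095 genes also include the differences between columns of the same library described above.

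The cultivars differed far more from each other than heat from control. In the control libraries, 17601 of 61670 genes (28.5%) were at least 2-fold higher in Arka Chaitra and 13331 (21.6%) in Matar Ageta. After heat the counts were 23365 (34.8%) and 14986 (22.3%) of 67190 genes. Among genes with at least 5 CPM in the higher control library, 54.2% lay within 2-fold of each other, while 2539 genes (8.52%) were at least 16-fold higher in Arka Chaitra and 1548 (5.19%) at least 16-fold higher in Matar Ageta. Of the 2539, 1969 had 3 counts or fewer in the Matar Ageta control. Of the 1548, 739 had 3 counts or fewer in the Arka Chaitra control. Single columns give a background for such differences, among genes with at least 5 CPM in the higher column. Between the 2 columns of a library, 2.87% to 4.71% of genes were at least 16-fold apart in either direction. Between control columns of different cultivars the share was 15.4% to 19.6%. With at least 5 CPM in the higher heat library, 4523 genes (14.6%) were at least 16-fold higher in Arka Chaitra after heat. In Matar Ageta 1638 (5.30%) were. Of the genes at least 16-fold apart in the controls, 77.7% of those higher in Arka Chaitra and 72.7% of those higher in Matar Ageta were also 16-fold apart in the same direction after heat. In the edgeR fit of all 4 libraries with treatment as a block, 0 genes were higher and 0 lower in Arka Chaitra at an adjusted p of 0.05, the smallest adjusted p being 0.206. At an unadjusted p of 0.05 there were 10935 genes, against 3857 from chance alone. DESeq2 with the same design called 7144 genes higher in Arka Chaitra and 2492 higher in Matar Ageta, and edgeR without the block called 2797 and 2580. DESeq2 was given all 127533 genes and gave no adjusted p for 65098 of them, whereas edgeR tested 77137.

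The differences followed the cluster number in the gene identifiers. The numbers were divided into 70 windows of 1000. In 28 windows, which form 4 unbroken runs, genes at least 16-fold higher in the Arka Chaitra control outnumbered those 16-fold higher in the Matar Ageta control, at 13.7% against 0.908% of genes. In the other 42 windows, also in 4 runs, the shares were 2.69% and 9.99%. The heat comparisons followed the same windows in opposite directions. In the first kind of window, 9416 genes were at least 2-fold higher after heat in Arka Chaitra and 2153 lower, so 81.4% of the differences were increases, whereas in the second kind 3956 were higher and 6967 lower, or 36.2% increases. In Matar Ageta the increases made up 32.5% of the differences in the first kind (2403 higher, 4982 lower) and 52.9% in the second (5315 higher, 4725 lower). The mean log2 ratio of heat to control per window correlated with the excess of Arka Chaitra genes at r = 0.910 in Arka Chaitra (Spearman's rho 0.742) and at r = -0.849 in Matar Ageta (rho -0.724). The 2-sided permutation p was 1e-05 for r and for rho in each case, the smallest that the permutations can give, and 1.2e-05 after Benjamini-Hochberg adjustment over 6 such correlations. The control libraries that set the kind of a window also enter the heat ratios, and chance errors shared in that way would give the opposite sign in both cultivars. Neighbouring windows are alike, whereas the permutations treat all windows as exchangeable, so these p-values overstate the evidence. The windows were therefore also rotated against each other, and 1 of 70 rotations, the real one, reached each value. The highest other rotation came to 0.812 in size for Arka Chaitra and 0.741 for Matar Ageta. The 2 columns of a single library also differed along the windows, with r = 0.908 for the Arka Chaitra heat library, -0.833 for the Matar Ageta control and -0.736 for Matar Ageta heat. The highest other rotation came to 0.751, 0.716 and 0.702 in size for these libraries, so the margin was small for Matar Ageta heat. The Arka Chaitra control columns gave -0.122 (permutation p = 0.3). Within the first and second kind of window, the heat ratios of the cultivars correlated across genes at r = 0.0780 and 0.105. In the first and second kind, the number of genes higher in both cultivars was 2.49 and 3.41 times that of independent lists, and lower in both 1.18 and 2.23 times. Genes higher in Arka Chaitra and lower in Matar Ageta were at 1.29 and 2.23 times, and the reverse at 1.44 and 1.90 times.

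**Figure D2:**
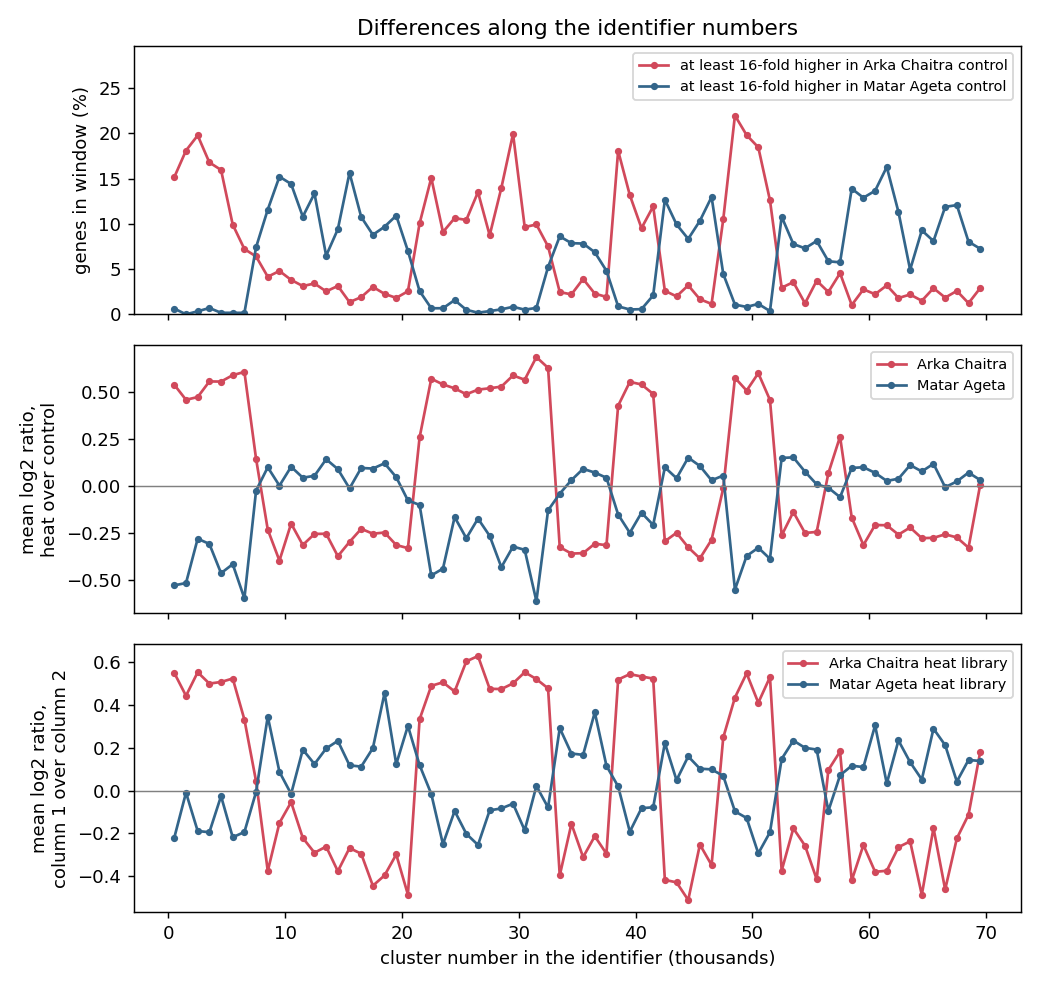
Values per window of 1000 cluster numbers (horizontal axis, cluster number divided by 1000), with windows in number order. The top panel gives the percentage of genes at least 16-fold higher in either cultivar's control library, the middle panel the mean log2 ratio of heat to control in each cultivar, and the bottom panel the mean log2 ratio of the 2 columns of each heat library; against the excess of Arka Chaitra genes in the top panel, r was 0.910 and -0.849 for the heat ratios of Arka Chaitra and Matar Ageta and 0.908 and -0.736 for the columns of their heat libraries.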

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

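The tests with windows of cluster numbers in this part were chosen only after the result was seen. The 2 cultivars differed in opposite directions for 1399 genes that were at least 2-fold higher after heat in the libraries titled Arka Chaitra and at least 2-fold lower in those titled Matar Ageta, and for 854 genes with the reverse. Both heat columns were on the same side of both control columns, in each cultivar's direction, for 434 of the 1399 and 194 of the 854. The same held for 447 of 1450 genes higher in both cultivars and for 413 of 1138 genes lower in both. These genes were picked from the sums of the same columns, so the order of the columns is no independent support. Within 1 cultivar alone, 43.3% to 55.4% of the genes counted in a direction had their columns in that order. Each group is 1 library, and the difference between the cultivars' responses was not tested for any gene. In the windows rich in genes found mainly in Arka Chaitra lay 71.6% of the 1399 and 22.1% of the 854, against 48.2% of all genes measured in both cultivars; independent lists with each cultivar's own counts per kind of window would put 81.4% and 27.4% there. With the Matar Ageta results shuffled over genes within each window, 100 shuffles gave 889 to 1023 genes for the first set and 425 to 524 for the reverse. The 1399 were 1.44 times the mean of the shuffles. The shuffles treat all genes of a window alike. They cannot decide whether the run structure of the identifiers is the whole cause, because that structure may act on only some genes of a window. With the shuffles also kept within 4 groups of equal size by mean expression, the ranges were 1042 to 1161 and 561 to 664. The excess was not specific to opposite differences, since genes higher in both cultivars (1450) and lower in both (1138) also lay above these last shuffles, which reached at most 815 and 787. The run structure stays open as a cause. A difference in heat response between the cultivars and variation between libraries stay open too, and neither of these can be tested with 1 library per group.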

How the results depend on the processing

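The alternatives with single columns, cluster sums, columns as separate libraries and windows were chosen after seeing the data. The counts of 2-fold differences between heat and control stayed within 1.5 times of the reported values under median-of-ratios size factors, total counts, a pseudocount of 1 CPM, the deposited signal table and each pair of single columns. In Arka Chaitra the excess of higher over lower genes depended on the heat column. Heat column 1 gave 18484 and 18356 higher genes against 11218 and 11221 lower. Heat column 2 gave 12275 and 12022 higher genes against 11237 and 11186 lower. Without a filter on low counts the higher genes of Matar Ageta grew from 7718 to 11721. With at least 10 CPM in the higher library, 1515 higher and 1371 lower genes were left in Arka Chaitra and 702 and 1248 in Matar Ageta. A filter of at least 10 CPM in the highest of the 4 libraries left 3600 and 1914 genes for a response larger in Arka Chaitra and in Matar Ageta. Most counted genes thus lie below these filters. With counts summed over each cluster number, 7349 clusters were higher and 6208 lower after heat in Arka Chaitra. In Matar Ageta 4463 clusters were higher and 6620 lower. Fewer units were counted, since clusters are fewer than genes. The correlation of the heat responses was 0.0292 without a filter, 0.119 at 10 CPM or more and 0.105 in the windows rich in Matar Ageta genes.

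For the edgeR tests, DESeq2 called 56 higher and 9 lower genes with heat, and 7144 genes higher in Arka Chaitra and 2492 in Matar Ageta. Without the block, edgeR called 2797 and 2580 genes for the cultivars; it still called 0 for heat, with 1927 higher and 1366 lower genes at an unadjusted p of 0.05. Leaving out any 1 library in turn, together with the block, gave 0 calls in every direction for heat and for cultivar; the lone library of a group is then assumed to vary like the others. If the 2 columns were separate libraries, which no label states, edgeR called 54 higher and 15 lower genes with heat in Arka Chaitra. It then called 0 and 0 in Matar Ageta, where 2156 and 2851 passed an unadjusted p of 0.05. The shared heat response gave 17 and 1 calls, a larger response in Arka Chaitra 35 and in Matar Ageta 18, and the cultivar difference 6683 and 5915. The cause of these differences was not tested. No paired analysis was possible because the titles give number 1 to both controls and number 2 to both heat libraries, so the number is the treatment. The planned tests of gene lists were not run. Depth limits genes under about 1 CPM, or 23.0 to 33.5 reads.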

Other observations

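The tests in this part were all chosen after the result was seen. Genes found mainly in Arka Chaitra and genes found mainly in Matar Ageta alternated along the identifier numbers. Among genes alone in their cluster, 8.64% were at least 16-fold higher in the Arka Chaitra control and 5.11% in the Matar Ageta control. These shares were near those of genes in clusters of several genes (8.42% and 5.26%). Of the genes at least 16-fold higher in 1 control, 45.4% of those higher in Arka Chaitra and 44.0% of those higher in Matar Ageta were alone in their cluster. There, reads cannot be split between separately assembled alleles of the same cluster. For genes in clusters of several genes such a split stays open: only 3 clusters held genes of both kinds, within the 1 to 14 of 100 shuffles within windows, but summing these clusters lowered the shares at least 16-fold apart from 8.42% and 5.26% of genes to 6.26% and 3.79% of clusters. The shares of a technical structure of the assembly or of the read assignment and of a difference between the cultivars in this pattern cannot be told apart. Columns of a single library share cultivar and treatment, so a cultivar difference alone was taken to leave no pattern between them. A technical structure was taken to leave the pattern in every library. Neither held throughout. The columns followed the windows in 3 of the 4 libraries (r = 0.908 for Arka Chaitra heat, -0.833 for the Matar Ageta control and -0.736 for Matar Ageta heat) and not in the Arka Chaitra control (r = -0.122). The highest other rotation came to 0.751, 0.716 and 0.702 in size in these 3 libraries. For them, the values argue against a cultivar difference as the whole cause of the differences along the windows. The Arka Chaitra control does not decide on a technical structure, since 2 columns affected alike would leave no pattern. Between the 2 kinds of window the mean log2 ratio of the columns shifted by 0.76 in size in Arka Chaitra heat and 0.36 in the Matar Ageta control. It shifted by 0.28 in Matar Ageta heat and 0.03 in the Arka Chaitra control. Between the cultivars the shift was 1.96 in the controls and 2.70 after heat. The ratio of heat to control shifted by 0.75 in Arka Chaitra and 0.39 in Matar Ageta. What the 8 runs represent was not analysed here, and alleles or copies placed in different clusters stay open too.

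The share of counts in the windows rich in Arka Chaitra genes differed between columns of the same treatment. It was 61.0% and 61.8% in the Arka Chaitra control, 65.7% and 62.4% in Arka Chaitra heat, 46.9% and 49.5% in the Matar Ageta control, and 45.3% and 46.7% in Matar Ageta heat.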
